A study of Oryza sativa with 12 samples.

How the data were processed

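Total RNA from leaf blades of rice (Oryza sativa) was sequenced as mRNA libraries in 12 samples. The samples formed 4 groups of 3: wild type (WT) and Oshmgb1 mutant plants, each with high or low phosphate (Pi). Per the labels, all seedlings grew with high Pi for 14 d and then for 7 d with high or low Pi, under 12 h of light at 30 °C and 12 h of darkness at 22 °C. Libraries were made from 1 µg of RNA with a NEBNext Ultra RNA kit, per the labels' protocols. The design text gives 200 µM for the high and for the low Pi condition alike, so the concentration used for low Pi is not clear here. Nothing in the labels states that the replicates came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical.

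The deposited tables gave FPKM (fragments scaled to transcript length and to the number of mapped fragments) for each library, per the file headers. The submitters' processing notes name CASAVA 2.17, HISAT2 2.0.5 and StringTie 1.3.6; the genome build, the annotation and the handling of reads that map to several loci are not given in the sources used here. Each of 4 tables held 32846 genes with MSU-style locus identifiers. Every library stood in 2 tables, and its FPKM values were identical in both for 12 of 12 libraries. The tables also held the authors' log2 fold, which they deposited as the log2 of the ratio of group means, and the authors' p-value and q-value, printed to 2 decimals. The fold column of the WT table held 1383 cells that were not numeric. The test behind the authors' p-values is not given in the sources used here. Further, 2 columns without a label held 6 filled cells and were not used.

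No read counts were analysed here, so sequencing depth is unknown and no counting interval was computed. To look for steps of single reads, ratios of low values (FPKM 0.1 to 1) were compared over 66 pairs of libraries, with a median of 58 genes per pair. The fullest window of ± 0.05 on the log2 scale held a median of 11.7% and at most 17.7% of the ratios, so no step was found from which relative depth could be read. Among 1662 genes with a median FPKM of 50 or more, 0 were listed at 0 in any library.

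Gene names were taken from the descriptions in the deposited tables. The supplied gene table (assembly ASM3414082v1) matched 0 of the identifiers, and 9758 genes were described only as expressed protein. The files pair no gene symbol with the identifiers. LOC_Os06g51220, described as HMG1/2, was taken as OsHMGB1 from knowledge outside the files, and values are given for every locus with that description. Coordinates were not used here. Reads shared among near-identical copies, such as histone genes, paired ferritin loci and nuclear copies of plastid genes, could not be assigned with certainty, and values of such loci are uncertain to that extent.

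The comparisons, the test, the named-gene rule, the gene lists and most alternatives were fixed before the data were examined. The design had foreseen counts first and FPKM as the other case; the files held FPKM, so the test foreseen for FPKM was used. Values were transformed as log2(FPKM + 1), and 17630 genes with FPKM of at least 1 in at least 3 libraries were tested. A fold on this scale understates the change of weakly expressed genes. One linear model over 12 libraries was fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes moderated test with a mean trend, two-sided), without a block. Its 5 contrasts were low against high Pi in WT, low against high Pi in the mutant, mutant against WT at high Pi, mutant against WT at low Pi, and the interaction, which is the low-Pi response of the mutant minus that of WT. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and calls were counted again at an absolute log2 fold of at least 1. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9. Values are given as mean ± SD in FPKM over n = 3 libraries, log2 folds with their standard error (SE) where stated.

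Genes named in the text followed a rule. It took LOC_Os06g51220 and, per contrast, the 8 largest positive and the 8 largest negative folds among called genes with an informative description, mean FPKM of at least 1 and no overlap between the libraries of the groups (5 and 5 for the interaction, where overlap was not considered). Of each list described it took up to 4 members with the smallest p. Any gene named outside this rule was chosen after its values were seen and is marked so.

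The 28 lists fixed beforehand were matched by description alone, since 0 of their members matched by symbol or by RAP identifier. They covered Pi and membranes (low-Pi signalling and SPX genes, phosphate transport, purple acid phosphatases, membrane lipid remodelling, S-like ribonucleases). They covered metabolism (photosystem and light harvesting, Calvin cycle, chlorophyll metabolism, sugar and starch, nitrogen, iron) and hormones (jasmonate, abscisic acid, gibberellin and brassinosteroid, auxin, cytokinin and strigolactone, ethylene). Further lists covered defence and phytoalexin, cell wall and expansin, heat shock and chaperone, oxidative stress, HMG-box and chromatin proteins, core histone with replication and mitosis, ribosomal proteins, and circadian clock. Other cell types and organs were covered by markers of root, of vascular tissue and lignin, and of cuticle and epidermis. Of these, 27 had tested genes. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. They were tested against no change with fry. For these lists, p-values were adjusted over the 27 fixed lists of a contrast. With an estimated correlation, camera called 0 of the 27 lists in each of the 5 contrasts, with lowest adjusted p of 0.18, 0.505, 0.824, 0.474 and 0.677. The direction of camera's test differed from the sign of the median or of the mean in 11, 8, 5, 4 and 9 lists of the 5 contrasts in the order above, where the lowest adjusted p was 0.3, 0.574, 0.468, 0.319 and 0.671. After the data had been seen, 6 lists were added (ZIM domain, morning clock, day and evening clock, copies of plastid-encoded photosystem genes, nuclear-encoded photosystem genes, iron deficiency by GO), as were the GO and KEGG terms of the files. Within a contrast, p-values of the added lists were adjusted over these 6 alone, and those of the terms over the terms. The adjusted p of an added list thus carries a lighter correction than that of a fixed list.

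Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a block for the replicate number, a fit to only the 6 libraries of a comparison, and each library left out in turn. Median-of-ratios and upper-quartile scaling of FPKM and a filter at FPKM 5 were added after the data had been seen. The procedure was tested on simulated data over 17630 genes with 100 genes changed by a log2 fold of 1 and 100 by 2. It recovered 76% and 98% for low against high Pi in WT, 74% and 97% in the mutant, 75% and 100% for the mutant at high Pi, 74% and 99% at low Pi, and 49% and 93% for the interaction. False calls made up 5.95%, 5%, 6.91%, 5.98% and 4.7% of calls in that order. The changed genes had a mean log2(FPKM + 1) of at least 2, so recovery of weaker genes was not tested. For the contrast in WT, 27 simulated lists of 60 genes were also tested: the 1 list shifted by 0.4 was called, and 0 of the others were. Each simulated gene varied independently of the others, unlike genes of real lists. The simulation therefore cannot show how often camera falsely calls lists whose genes vary together. Nor can it show the rate of false gene calls where a library deviates in many genes at once.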

Results

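Expression was measured in leaf blades of 21 d old rice seedlings in a design that crossed genotype with Pi supply: WT and Oshmgb1 mutant plants, at high and at low Pi, with 3 libraries in each of 4 groups. HMGB proteins are abundant chromatin proteins that bind and bend DNA, and the series concerns the part OsHMGB1 plays in Pi homeostasis and growth. FPKM values summed to between 549457 and 583292 per library, and 16093 to 16976 genes per library reached an FPKM of at least 1. The 10 most abundant genes held 12.5 to 15.6% of the total. The first principal component took 33.1% of the variance and ran from mutant at high Pi (scores −42.7 to −31.3) through WT at high Pi (−14.4 to −10.3) and mutant at low Pi (3.71 to 17.7) to WT at low Pi (37.0 to 40.3). On the second component (25.1%), the mutant libraries at low Pi stood apart from the rest (−40.7 to −34.1). Within groups, the median SD on the log2 scale was 0.148 for WT at high Pi, 0.151 for WT at low Pi, 0.173 for the mutant at high Pi and 0.133 for the mutant at low Pi.

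To check the labels, the targeted gene was examined first. LOC_Os06g51220, taken here as OsHMGB1 from knowledge outside the files, stood at 1232 ± 68.2 FPKM in WT and 539 ± 19.4 in the mutant at high Pi, and at 1895 ± 219 in WT and 678 ± 78.7 in the mutant at low Pi. Its transcript fell in the mutant at high Pi (log2 fold −1.19, SE 0.13, adjusted p = 0.00257) and at low Pi (−1.48, adjusted p = 0.000266). Each of the mutant libraries (516.41 to 725.71 FPKM) lay below each of the WT libraries (1176.75 to 2146.98). The transcript was reduced and not absent in all 6 mutant libraries; which part of the gene the mutation affects is not given in the sources used here. In WT it rose at low Pi (0.62, adjusted p = 0.0121). This call was lost without WT low-Pi library 3 (0.52, adjusted p = 0.0577), with no filter or in a fit to the 6 libraries (0.0517 in both). Over all alternatives the adjusted p ran from 0.00705 to 0.0577. The response in the mutant was 0.33 (adjusted p = 0.113), and the interaction was −0.29 (SE 0.19, adjusted p = 0.457). Of the other loci described as HMG1/2, LOC_Os09g37910 rose in the mutant at high Pi from 31.8 ± 4.21 to 146 ± 28.9 FPKM (2.15, SE 0.28, adjusted p = 0.00561) and stood at 45.2 ± 18.5 in WT and 78.1 ± 19.0 in the mutant at low Pi (0.83, adjusted p = 0.0649). LOC_Os04g47690 stood between 168 and 194 FPKM in the 4 group means, LOC_Os01g47600 between 7.55 and 9.59, LOC_Os02g44930 between 4.54 and 7.70, and LOC_Os02g15810 and LOC_Os08g01100 below 0.39.

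**Figure D1:**
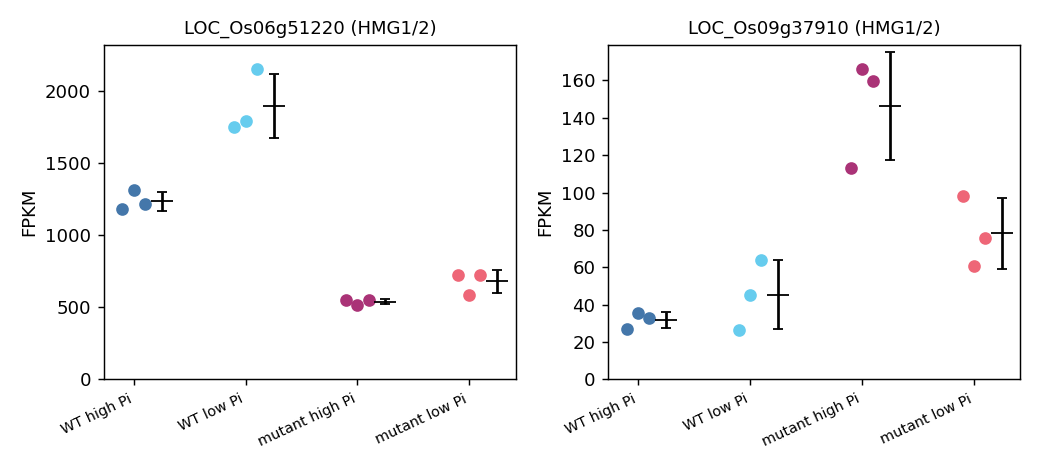
FPKM (y axis, linear from 0) of LOC_Os06g51220 and LOC_Os09g37910 in each of the 12 libraries, by group on the x axis; points are libraries, and bars show mean ± SD of 3. LOC_Os06g51220 had a mean of 539 FPKM in the mutant against 1232 in WT at high Pi, whereas LOC_Os09g37910 had 146 against 31.8.

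To describe how WT leaf blades responded to the lower Pi supply, low Pi was compared with high Pi within WT. The hour of harvest is not given in the sources used here, and clock genes moved with Pi level in both genotypes, as described below. Differences between Pi levels in either genotype may therefore include an effect of the hour, which was not separated from Pi supply. LOC_Os07g34570, described only by a FAD-dependent oxidoreductase domain, rose from 17.9 ± 6.01 to 1217 ± 363 FPKM (log2 fold 6.01, SE 0.35, adjusted p = 3.58e-06). The thiamine biosynthesis gene thiC (LOC_Os03g47610) rose from 1.99 ± 0.74 to 61.3 ± 10.3 (4.40, SE 0.20, adjusted p = 6.54e-07) and the RING-H2 finger protein LOC_Os01g60730 from 1.28 to 43.98 FPKM (4.32, adjusted p = 2.18e-06). LOC_Os02g31030, a glycerophosphodiester phosphodiesterase, an enzyme that splits products of phospholipid breakdown, rose from 0.61 ± 0.28 to 28.9 ± 29.9 (3.71, adjusted p = 0.00129), with an SD as large as the mean at low Pi. In the other direction, the metal transporter Nramp6 (LOC_Os07g15460) fell from 127 ± 32.7 to 0.63 ± 0.07 (−6.26, SE 0.52, adjusted p = 4.12e-05). The bHLH transcription factors LOC_Os01g72370 (76.2 to 0.81 FPKM, −5.50, adjusted p = 1.2e-05) and LOC_Os03g26210 (43.0 to 4.39, −3.02, adjusted p = 2.03e-06) fell as well. The MYB gene LOC_Os08g06110, which the files assign to the orthology group of the clock gene LHY, fell from 275 ± 20.9 to 37.7 ± 8.90 (−2.85, adjusted p = 1.82e-06). A membrane protein (LOC_Os03g15910), a DnaJ protein (LOC_Os01g42190), DSP1 (LOC_Os01g50622) and a chloroplast DAG protein (LOC_Os08g04450) rose by log2 folds from 2.87 to 3.36. A retrotransposon protein (LOC_Os07g04930), a transcriptional regulator (LOC_Os10g18370), OsCttP2 (LOC_Os02g57060) and a peptide transporter (LOC_Os01g65100) fell, with log2 folds from −5.94 to −2.56.

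Among lists tied to Pi, both tested low-Pi signalling and SPX genes rose in WT (2 adjusted over the list alone). The camera adjusted p was 0.078, and 0.0395 after median-of-ratios scaling, but 0.6 with an estimated correlation in the unscaled fit. SPX domains bind inositol phosphates and act in Pi sensing. LOC_Os02g10780 rose from 5.65 ± 1.78 to 52.9 ± 46.8 FPKM (2.67, adjusted p = 0.00548) and LOC_Os06g40120 from 8.58 to 41.9 (1.91, adjusted p = 0.0166). Of 5 phosphate transport genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.828). The chloroplast transporter LOC_Os02g38020 fell from 100.2 to 44.8 FPKM (−1.18, adjusted p = 0.00214). LOC_Os06g29790 rose from 4.34 to 7.70 (0.71, adjusted p = 0.0161), but its call was lost without WT high-Pi library 3 (0.0566), WT low-Pi library 2 (0.0552) or WT low-Pi library 3 (0.0594), within a range of 0.0132 to 0.0594 over the alternatives. The other rise, in LOC_Os04g10750 (0.65, adjusted p = 0.0429), was lost without any 1 of WT high-Pi libraries 1 to 3 (0.122, 0.0965 and 0.0665) or WT low-Pi libraries 1 to 3 (0.11, 0.107 and 0.0717). It was also lost without mutant high-Pi library 1 (0.0534) or 2 (0.0549) or mutant low-Pi library 1 (0.0603), with no filter (0.0783), with the filter at FPKM 5 (0.0522) and under both scalings (0.0728 and 0.0557). Of 2 purple acid phosphatases, enzymes that release Pi from organic esters, LOC_Os01g56880 rose from 5 ± 0.17 to 11.2 ± 2.65 (1.00, adjusted p = 0.0025), and LOC_Os12g44030 stood at 0.38 (adjusted p = 0.0926); adjusted over the list alone, both passed (camera adjusted p = 0.12). Of 13 membrane lipid remodelling genes, 5 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.684). The digalactosyldiacylglycerol synthase LOC_Os11g05990 fell from 40.1 to 13.5 FPKM (−1.50, adjusted p = 0.000112), and the phosphodiesterase LOC_Os08g42390 rose (0.99, adjusted p = 0.00984). The other fall, in LOC_Os02g33580 (adjusted p = 0.0143), was lost without WT high-Pi library 1 (0.0526) or WT low-Pi library 3 (0.0647).

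Members of metabolic and hormone lists were also called in WT. All 3 tested genes of the iron homeostasis list, a nicotianamine synthase and 2 ferritins matched by description, rose (3 adjusted over the list alone, median 1.27). The camera adjusted p was 0.0111, and 0.457 with an estimated correlation. The metal transporter Nramp6 lay outside the list and fell from 127 to 0.63 FPKM. Iron deficiency genes by GO, added later, had a median of −0.02, so the rise does not describe iron genes at large. Genes that the list named by symbol only, the IRO genes among them, were not matched. Their direction is therefore not part of this count. Nicotianamine synthase LOC_Os07g48980, which makes an iron chelator, went from 0.25 ± 0.03 to 1.27 ± 0.16 FPKM (0.85, adjusted p = 0.000828). The ferritin gene LOC_Os12g01530 rose from 25.8 to 65.1 (1.27, adjusted p = 0.0193), a call lost without WT high-Pi library 2 (0.0635) or WT low-Pi library 1 (0.0672) and otherwise as low as 0.00233 over the alternatives. The ferritin gene LOC_Os11g01530 stood at 1.33 (adjusted p = 0.0441), a call lost in 10 of 12 fits without 1 library, all but those without mutant high-Pi library 2 or 3. Its adjusted p reached 0.136 without WT high-Pi library 1, and was 0.0781 with no filter and 0.0632 and 0.0557 under the scalings. Of 18 cytokinin and strigolactone genes, 6 fell (6 adjusted over the list alone; median −0.37, camera adjusted p = 0.00213, and adjusted p = 0.18 with an estimated correlation). These included the cytokinin O-glucosyltransferases LOC_Os04g25440 (82.2 to 50.1 FPKM, −0.70, adjusted p = 0.000656) and LOC_Os02g51910 (−1.24, adjusted p = 0.00306) and the N-glucosyltransferase LOC_Os11g25454 (−0.67, adjusted p = 0.00315), enzymes that attach glucose to cytokinins. Of 17 nitrogen genes, 1 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.502, downward against a median of 0.12). A glutamate synthase (LOC_Os05g48200) rose from 28.2 ± 10.7 to 193 ± 7.35 FPKM (2.79, adjusted p = 0.00014), and an ammonium transporter (LOC_Os04g43070) fell from 71.4 ± 13.2 to 21.9 ± 4.56 (−1.67, adjusted p = 0.00014). The other falls, in LOC_Os03g02030 (adjusted p = 0.0269) and LOC_Os02g50240 (0.0276), were lost without WT high-Pi library 2 (0.0628 and 0.0747) or 3 (0.0515 and 0.0915) or WT low-Pi library 1 (0.0868 and 0.0816). The former was also lost without WT high-Pi library 1 (0.0851) or WT low-Pi library 2 (0.0653) and in a fit to the 6 libraries (0.065), and the latter without WT low-Pi library 3 (0.101).

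Of 68 photosystem and light-harvesting genes, 12 fell and 1 rose in WT (22 and 1 adjusted over the list alone; median −0.40, camera adjusted p = 2.19e-07, and adjusted p = 0.218 with an estimated correlation). The photosystem II protein Z locus LOC_Os04g16876 fell from 6.05 to 1.34 FPKM (−1.64, adjusted p = 0.00326) and PSB28 (LOC_Os01g71190) from 36.9 to 17.7 (−1.02, adjusted p = 0.00196), and the chlorophyll a/b-binding gene LOC_Os09g26810 rose (1.13, adjusted p = 0.000349). Of these genes, 36 were described as products that the plastid genome encodes, although the list was meant for nuclear genes. In a division made after the data had been seen, 9 of these copies fell (median −0.62), and of the 32 others 3 fell and 1 rose (median −0.03). Of 59 core histone, replication and mitosis genes, which mark dividing cells, 13 rose (21 adjusted over the list alone; median 0.31, camera adjusted p = 0.00376, and adjusted p = 0.711 with an estimated correlation). The histone gene LOC_Os10g39410 rose from 127 ± 20.8 to 384 ± 203 FPKM (1.47, adjusted p = 0.00945) and the kinesin gene LOC_Os07g01490 by 0.92 (adjusted p = 0.00183).

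In WT, limma called 2345 of 17630 genes (13.3%): 1487 rose and 858 fell, of which 269 and 268 passed a log2 fold of 1. Of the called genes, 2334 had no overlap between the groups, which a call at this group size nearly implies. Among all tested genes this held for 32.6%, against 10% by chance. Here and below, 10% is the average over splits of 3 against 3 libraries. Genes vary together, so a single chance split can lie far from it. The balance of directions depended on scaling, with 1068 up and 1180 down after median-of-ratios scaling and 1313 up and 975 down after upper-quartile scaling (63.4, 47.5 and 57.4% up). The count fell to 1147 without WT low-Pi library 3 and to 1416 without WT high-Pi library 2. With a pseudocount of 0.1, 429 rises and 362 falls passed a log2 fold of 1.

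The same comparison was made within the mutant. LOC_Os07g34570 rose from 6.06 ± 3.61 to 659.6 ± 34.4 FPKM (log2 fold 6.68, SE 0.35, adjusted p = 1.12e-06), thiC from 1.05 to 34.0 (4.11, adjusted p = 7.04e-07) and a glycolipid transfer protein (LOC_Os04g35790) from 2.98 to 45.9 (3.63, adjusted p = 0.000235). LOC_Os02g31030 (3.27), an RNA polymerase sigma factor (LOC_Os05g51150, 3.20), LOC_Os01g60730 (3.01) and LOC_Os08g04450 (2.99) rose as well. The F-box gene OsFBX404 (LOC_Os11g09590) was listed at 0 in all 6 high-Pi libraries, at 0.09, 0 and 0 FPKM in WT at low Pi, and at 11.33, 32.73 and 76.43 in the mutant at low Pi. The bHLH gene LOC_Os01g72370 fell from 65.7 ± 41.4 to 0.07 ± 0.04 FPKM (−5.78, adjusted p = 7.03e-06), and LOC_Os03g26210 fell from 72.9 to 2.83 (−4.25, adjusted p = 2.34e-07). Nramp6 fell by 4.92 (63.8 ± 69.0 to 0.48 ± 0.07 FPKM, adjusted p = 0.000178), with unequal libraries at high Pi. A late embryogenesis abundant protein (LOC_Os01g21250) fell from 255 to 15.01 FPKM (−4.03, adjusted p = 0.00285) and a cytochrome P450 (LOC_Os02g47470) from 29.2 to 1.63 (−3.20, adjusted p = 0.0036). The retrotransposon protein LOC_Os07g04930, OsCttP2 and LOC_Os10g18370 fell with log2 folds from −4.88 to −2.86. Mutant libraries at high Pi were unequal for LOC_Os01g72370 and for LOC_Os07g04930 (35.9 ± 30.5 FPKM) as well.

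In the mutant, 1 of 2 low-Pi signalling and SPX genes rose (2 adjusted over the list alone; camera adjusted p = 0.223). LOC_Os02g10780 went from 7.20 to 31.7 FPKM (1.99, adjusted p = 0.018), a call lost without mutant high-Pi library 3 (0.0509), mutant low-Pi library 1 (0.0605) or mutant low-Pi library 3 (0.0529) and as low as 0.00181 over the alternatives. Both purple acid phosphatases rose (2 adjusted over the list alone; median 1.03, camera adjusted p = 0.0464, and adjusted p = 0.505 with an estimated correlation), LOC_Os01g56880 by 1.38 (adjusted p = 0.000315) and LOC_Os12g44030 by 0.68 (adjusted p = 0.00608). Of 5 phosphate transport genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone; median −0.26, mean 0.08, camera upward with adjusted p = 0.68). LOC_Os06g29790 rose from 4.41 to 10.8 FPKM (1.13, adjusted p = 0.00106), and LOC_Os04g10750 rose by 1.13 (adjusted p = 0.00223). The fall, in LOC_Os02g38020 (−0.62, adjusted p = 0.0404), was lost without mutant high-Pi library 2 (0.129) or 3 (0.0904), or mutant low-Pi library 1 (0.0769), 2 (0.118) or 3 (0.0867). It was also lost without WT high-Pi library 3 (0.0518) or WT low-Pi library 2 (0.0532) and with no filter (0.0669). All 3 tested genes of the iron list, matched by description alone, rose (3 adjusted over the list alone, camera adjusted p = 0.0464, and 0.767 with an estimated correlation). Among them was nicotianamine synthase (0.64, adjusted p = 0.00317), whereas Nramp6, outside the list, fell. The calls of the ferritin genes LOC_Os11g01530 (adjusted p = 0.0275) and LOC_Os12g01530 (0.0308) were lost without mutant high-Pi library 1 (0.0721 and 0.083) or 2 (0.1 and 0.114) or mutant low-Pi library 1 (0.0706 and 0.0805) or 3 (0.0892 and 0.103). They were also lost with no filter (0.0521 and 0.057) and in a fit to the 6 libraries (0.0674 and 0.0834). The camera calls of the purple acid phosphatases and of the iron genes were lost under both scalings of FPKM (adjusted p = 0.0644 and 0.0638). Of 13 lipid genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.739), including LOC_Os11g05990 (−0.95, adjusted p = 0.0015). Of 18 cytokinin and strigolactone genes, 2 rose and 6 fell (2 and 7 adjusted over the list alone; median −0.34, camera adjusted p = 0.128), and LOC_Os04g25440 fell by 1.00 (adjusted p = 6.87e-05). Of 68 photosystem genes 1 rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.68), and of 59 core histone, replication and mitosis genes 5 rose and 7 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.443).

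In the mutant, limma called 3307 genes (18.8%), 1847 up and 1460 down, with 396 and 256 past a log2 fold of 1. Of these, 3255 had no overlap between groups (37.5% of all tested genes, against 10% by chance). The count fell to 1984 without mutant low-Pi library 2 and to 2016 without mutant high-Pi library 2, and that of falls to 969 without mutant low-Pi library 1. With a pseudocount of 0.1, 659 rises and 402 falls passed a log2 fold of 1.

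To see how far the responses of the genotypes coincided, their folds and calls were compared; the pair of comparisons shares no library. Genes that rose in both numbered 776, against 155.8 expected from independent lists, and genes that fell in both 376, against 71.1. Another 126 genes moved in opposite directions, for which no expected number was computed. The same model over 12 libraries gave each gene a single variance for both comparisons. Genes with a small variance are therefore more easily called in both, so the lists are not independent and the expected numbers may be too low. With each library left out in turn, the genes called in both in the same direction ran from 734 to 1144, against 1152 with all libraries. Across genes, which are not independent replicates, the folds correlated with Pearson r = 0.462 and Spearman rho = 0.335. LOC_Os07g34570, thiC, LOC_Os01g72370 and LOC_Os03g26210 were among the shared genes.

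**Figure D2:**
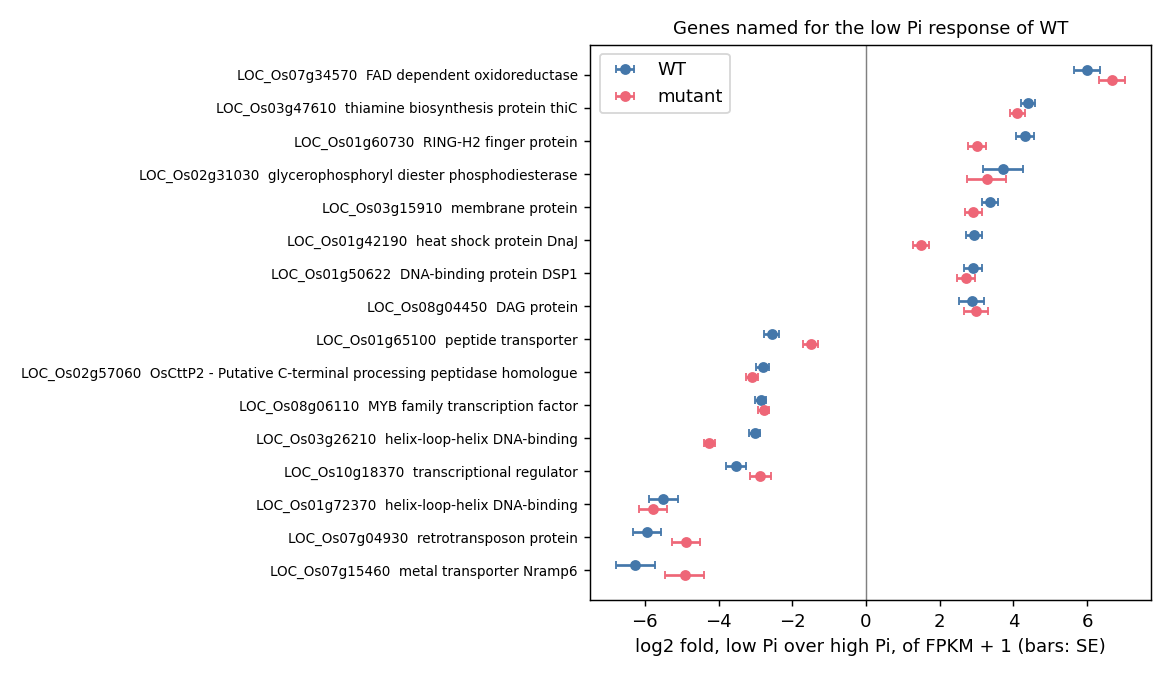
Log2 fold of low against high Pi on the log2(FPKM + 1) scale (x axis) for the 16 genes named for the WT response (y axis), in WT (blue) and in the mutant (red); points are limma estimates from 3 libraries per group and bars are SE. LOC_Os07g34570 rose by 6.01 in WT and 6.68 in the mutant, and Nramp6 (LOC_Os07g15460) had folds of −6.26 and −4.92.

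To find genes that differed between genotypes at ample Pi, the mutant was compared with WT at high Pi. Whether differences from WT, here and at low Pi, come from the loss of OsHMGB1 itself was not tested. A pathogenesis-related Bet v I family gene (LOC_Os08g28670) fell in the mutant from 7.55 ± 1.42 to 0.71 ± 0.34 FPKM (log2 fold −2.33, SE 0.16, adjusted p = 0.000211), and a short-chain dehydrogenase/reductase (LOC_Os04g44924) from 79.8 ± 11 to 17.5 ± 9.61 (−2.24, SE 0.36, adjusted p = 0.0119). The NAM transcription factor LOC_Os01g23710 fell from 17.3 to 2.55 (−2.61, adjusted p = 0.0088), a call that was lost in a fit to the 6 libraries alone (0.0674; range 0.000651 to 0.0674 over the alternatives). Apart from LOC_Os09g37910, genes that rose included an F-box interaction domain protein (LOC_Os10g41838, 1.87 to 7.89 FPKM, 1.63, adjusted p = 0.00342) and anthranilate phosphoribosyltransferase (LOC_Os04g58720, 0.43 to 3.02, 1.48, adjusted p = 0.00252). A disease resistance protein of the RPM1 type (LOC_Os11g12340, 12.5 to 33.9, 1.38, adjusted p = 0.01) and a GRAS transcription factor (LOC_Os01g71970, 6.13 ± 1.82 to 16.0 ± 2.06, 1.28, adjusted p = 0.00746) rose as well. The naming rule also took the osmotin LOC_Os12g38170 (−2.30, adjusted p = 0.0459) and the Cf-2 gene LOC_Os01g06876 (−2.23, adjusted p = 0.0398). Further rises it took were a flavin monooxygenase (LOC_Os01g25470, 1.84, adjusted p = 0.0457) and Os4bglu15 (LOC_Os04g43380, 1.21, adjusted p = 0.0178). Their calls were lost in 9, 8, 10 and 2 of 12 fits without 1 library, and under other settings as well.

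Of 17 jasmonate genes, 3 fell in the mutant at high Pi (6 adjusted over the list alone; median −0.29, camera adjusted p = 0.0245, and adjusted p = 0.824 with an estimated correlation), among them the oxophytodienoate reductase LOC_Os01g27230 (17.5 ± 1.52 to 9.51 ± 1.17 FPKM, −0.82, adjusted p = 0.0127), an enzyme of jasmonate synthesis. The calls of the other 2, LOC_Os12g05020 (adjusted p = 0.0353) and LOC_Os03g32314 (0.0476), were lost without WT high-Pi library 1 (0.0779 and 0.118), 2 (0.1 and 0.0633) or 3 (0.071 and 0.0958) or mutant high-Pi library 2 (0.0623 and 0.0866) or 3 (0.0962 and 0.137). They were also lost with no filter (0.0514 and 0.0754) and in a fit to the 6 libraries (0.0748 and 0.127). The former was lost without mutant high-Pi library 1 (0.0627), and the latter without WT low-Pi library 2 (0.0637) or mutant low-Pi library 1 (0.0695), 2 (0.0641) or 3 (0.0581). Of 108 oxidative stress genes, 2 rose and 5 fell (2 and 9 adjusted over the list alone; median −0.25, camera adjusted p = 0.0245, and adjusted p = 0.824 with an estimated correlation). A peroxidase (LOC_Os08g41090) fell from 23.1 ± 3.91 to 9.33 ± 1.19 (−1.22, adjusted p = 0.00257). Ascorbate peroxidase OsAPx7 (LOC_Os04g35520) rose from 11.2 to 21.6 (0.89, adjusted p = 0.017) except in a fit to the 6 libraries alone (0.0827; range 0.0117 to 0.0827). Among the falls, that of LOC_Os08g44770 (adjusted p = 0.0173) was lost without mutant high-Pi library 2 (0.0505), and that of LOC_Os04g59190 (0.0221) without WT high-Pi library 1 (0.0627) or 3 (0.0726) or mutant high-Pi library 3 (0.0644). Both were lost in a fit to the 6 libraries (0.0652 and 0.0594). Of 77 defence and phytoalexin genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone; median −0.26, camera adjusted p = 0.0245, and adjusted p = 0.824 with an estimated correlation). The gene that fell was LOC_Os08g28670, and the chitinase CHIT1 (LOC_Os02g39330) stood at −1.04 (adjusted p = 0.0576). The rise, in LOC_Os04g43760 (adjusted p = 0.023), was lost without WT high-Pi library 1 (0.058), 2 (0.0539) or 3 (0.075) or mutant high-Pi library 2 (0.0731) or 3 (0.0672). Of 59 core histone, replication and mitosis genes, 2 rose and 1 fell (4 and 2 adjusted over the list alone; median 0.17, camera adjusted p = 0.0473, and adjusted p = 0.824 with an estimated correlation). That camera call was lost under both scalings of FPKM (adjusted p = 0.0858 and 0.0935). The called genes were the histone genes LOC_Os09g38020 (1.26, adjusted p = 0.0488) and LOC_Os07g36140 (0.95, adjusted p = 0.0468) and the kinase gene CDKB (LOC_Os01g67160, −0.52, adjusted p = 0.049). Each missed the threshold when mutant high-Pi library 3 was left out (0.123, 0.13 and 0.139), the highest values over the alternatives. Each also missed it without mutant high-Pi library 2 (0.104, 0.106 and 0.126), WT high-Pi library 1 (0.113, 0.106 and 0.1), library 2 (0.114, 0.0962 and 0.116) or library 3 (0.087, 0.103 and 0.104). Of 13 HMG-box and chromatin protein genes, 1 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.806), these being LOC_Os09g37910 and LOC_Os06g51220. Of 39 ethylene genes, 4 fell (8 down and 1 up adjusted over the list alone; camera adjusted p = 0.222), including LOC_Os05g42180 (−0.90, adjusted p = 0.0088). The other 3, LOC_Os03g64280 (adjusted p = 0.0259), LOC_Os06g11860 (0.0321) and LOC_Os02g43790 (0.0416), were lost without WT high-Pi library 3 (0.0764, 0.0824 and 0.106), mutant high-Pi library 2 (0.0796, 0.0866 and 0.0742) or 3 (0.0753, 0.0973 and 0.12), and in a fit to the 6 libraries (0.0929, 0.0992 and 0.128). LOC_Os03g64280 was also lost without WT high-Pi library 2 (0.0634), and the others without WT high-Pi library 1 (0.088 and 0.0867) and with no filter (0.0605 and 0.0748). LOC_Os02g43790 was further lost without mutant high-Pi library 1 (0.0621), WT low-Pi library 2 (0.0515) or 3 (0.0525), or mutant low-Pi library 1 (0.0587) or 3 (0.0528).

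A list of ZIM domain genes, which encode repressors of jasmonate signalling, was added after the data had been seen, because 2 of them were among the largest falls. At high Pi 2 of 6 fell (6 adjusted over the list alone; median −1.77, camera adjusted p = 0.000185, and adjusted p = 0.352 with an estimated correlation). LOC_Os03g08330 stood at −3.43 (adjusted p = 0.0302) and LOC_Os10g25290 at −3.11 (adjusted p = 0.0303). Both calls were lost without WT high-Pi library 1 (0.0787 and 0.0711), WT high-Pi library 3 (0.073 and 0.076), mutant high-Pi library 1 (0.0578 and 0.0574) or mutant high-Pi library 3 (0.095 and 0.0959). In a fit to the 6 libraries alone, 1 of 3 other settings that ended each call, the adjusted p reached 0.124 and 0.126. Over all alternatives the folds ran from −4.35 to −2.77 and from −4.85 to −2.37.

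At high Pi, limma called 631 genes (3.58%), 230 up and 401 down, with 37 and 109 past a log2 fold of 1. All 631 had no overlap between groups (24.2% of tested genes, against 10% by chance). This count moved with single libraries: it was 215, 270 and 177 without WT high-Pi library 1, 2 or 3, and 214 and 241 without mutant high-Pi library 2 or 3. A fit to the 6 libraries alone called 103 genes, a block for the replicate number 312 (104 up and 208 down), and the filter at FPKM 5 left 417. Rises numbered 153 with no filter and 140 and 145 without mutant low-Pi library 1 or 2. Past a log2 fold of 1 there were 60 rises and 201 falls with a pseudocount of 0.1, 26 and 69 with no filter, 19 and 73 with the filter at FPKM 5, and 24 and 37 in the fit to 6 libraries. These were 24 and 67, 23 and 112, and 20 and 43 without WT high-Pi library 1, 2 or 3, and 55 and 190, 31 and 66, and 26 and 61 without mutant high-Pi library 1, 2 or 3. Of 30 called genes that the naming rule took in this comparison, 17 lost their call on leaving out 1 library.

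To find genes that differed between genotypes when Pi was low, the mutant was compared with WT at low Pi. The ZIM domain gene LOC_Os03g08330 fell in the mutant from 47.4 ± 19.2 to 0.69 ± 0.17 FPKM (log2 fold −4.75, SE 0.72, adjusted p = 0.00302), the cytochrome P450 LOC_Os02g47470 to 1.63 ± 0.21 (−4.56, adjusted p = 0.00158) and the bHLH gene LOC_Os03g53020 from 50.9 to 2.27 (−3.90, adjusted p = 0.00816). A C3HC4 zinc finger gene (LOC_Os02g52210, −4.22), the ZIM domain gene LOC_Os10g25290 (−3.75) and a U-box gene (LOC_Os02g33680, −3.44) fell as well, with adjusted p of 0.00246, 0.0054 and 0.00868. The KID-containing protein LOC_Os08g40510 rose from 19.0 ± 6.30 to 97.6 ± 3 FPKM (2.35, SE 0.22, adjusted p = 0.000334). HLS (LOC_Os03g55530) rose from 3.57 to 27.6 (2.60, adjusted p = 0.00367), and the auxin-induced OsSAUR39 (LOC_Os09g37330) from 1.99 to 13.4 (2.26, adjusted p = 0.00138). A beta-amylase (LOC_Os10g32810) rose from 1.80 to 12.4 (2.16, adjusted p = 0.00466), a thioredoxin (LOC_Os07g48510) from 2.73 to 14.1 (2.11, adjusted p = 0.0103) and an expansin (LOC_Os03g04020) from 19.7 ± 9.76 to 78.5 ± 5.58 (2.05, adjusted p = 0.00408). The naming rule also took OsFBX404 (4.95, adjusted p = 0.000334) and a ferroportin1 domain gene (LOC_Os06g36450, 2.31, adjusted p = 0.0312). Further falls it took were an amino acid transporter (LOC_Os01g41420, −3.33, adjusted p = 0.0222) and a bHLH gene (LOC_Os04g23550, −3.26, adjusted p = 0.0324). The calls of the ferroportin1, transporter and LOC_Os04g23550 genes were lost in 6, 4 and 5 of 12 fits without 1 library.

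Of 77 defence and phytoalexin genes, 4 rose and 20 fell in the mutant at low Pi (6 and 29 adjusted over the list alone; median −0.30, camera adjusted p = 0.134). LOC_Os08g28670 fell from 11.4 ± 1.37 to 1.74 ± 0.11 FPKM (adjusted p = 7.62e-05). WRKY15 (LOC_Os01g46800) fell from 9.58 ± 1.76 to 1.33 ± 0.39 FPKM (−2.18, adjusted p = 0.00244) and the chitinase CHIT16 (LOC_Os03g04060) from 14.2 to 2.89 (−1.96, adjusted p = 0.00389). Of 17 jasmonate genes, 5 fell (6 adjusted over the list alone; median −0.38, camera adjusted p = 0.186). Among them were the lipoxygenases LOC_Os05g23880 (18.2 ± 1.37 to 10.2 ± 1.38 FPKM, −0.79, adjusted p = 0.00676) and LOC_Os04g37430 (4.71 to 1.19, −1.36, adjusted p = 0.00922). All 6 ZIM domain genes fell (6 adjusted over the list alone; median −2.05, camera adjusted p = 4e-04, and adjusted p = 0.247 with an estimated correlation). Of 10 abscisic acid genes, 3 fell (4 adjusted over the list alone; camera adjusted p = 0.186), including the late embryogenesis abundant proteins LOC_Os05g08920 (−0.95, adjusted p = 0.00334) and LOC_Os05g50710 (−0.76, adjusted p = 0.00419). The third, LOC_Os01g21250 (−2.33, adjusted p = 0.0451), was lost without WT low-Pi library 2 (0.123) or 3 (0.147), mutant low-Pi library 1 (0.0594), 2 (0.102) or 3 (0.131), WT high-Pi library 3 (0.0557) or mutant high-Pi library 2 (0.0566). It was also lost with no filter (0.0799) and under both scalings (0.0594 and 0.0545). Of 108 oxidative stress genes, 6 rose and 11 fell (6 and 11 adjusted over the list alone; camera adjusted p = 0.876). Of 13 HMG-box and chromatin protein genes, 2 fell (2 adjusted over the list alone; camera adjusted p = 0.739), LOC_Os06g51220 and the SWI/SNF gene LOC_Os07g44800 (−0.81, adjusted p = 0.00766).

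**Figure D3:**
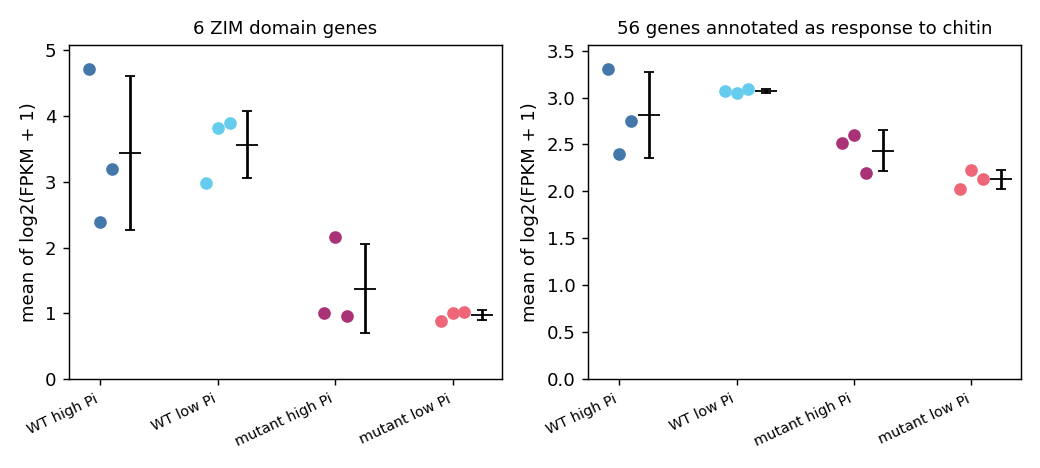
Mean of log2(FPKM + 1) over the 6 ZIM domain genes and over the 56 genes annotated with the response to chitin (y axis) in each library, by group on the x axis; points are libraries and bars show mean ± SD of 3. The ZIM means in WT at high Pi ranged from 2.39 to 4.70, and those of the mutant at low Pi from 0.89 to 1.03.

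Of 68 photosystem and light-harvesting genes, 28 rose and 2 fell in the mutant at low Pi (28 and 3 adjusted over the list alone; median 0.47, camera adjusted p = 3.97e-07, and adjusted p = 0.474 with an estimated correlation). Photosystem II protein Z at LOC_Os04g16876 rose from 1.34 to 8.55 FPKM (2.01, adjusted p = 0.00226) and the P700 apoprotein A2 copy LOC_Os10g38234 from 4.43 to 11.7 (1.25, adjusted p = 0.00321). The rise lay in the copies of plastid-encoded genes, of which 27 of 36 rose (28 adjusted over the list alone; median 0.99, camera adjusted p = 1.04e-21, and adjusted p = 0.117 with an estimated correlation). Of the 32 nuclear-encoded genes, 1 rose and 2 fell (median −0.25). Of 59 core histone, replication and mitosis genes, 1 rose and 13 fell (1 and 20 adjusted over the list alone; median −0.39, camera adjusted p = 0.128), including the histone genes LOC_Os01g05900 (−1.89, adjusted p = 0.00419) and LOC_Os07g36130 (−1.66, adjusted p = 0.00704). With library scaling the camera test of this list and of the defence list passed (adjusted p = 0.0282 with median-of-ratios and 0.0442 with upper-quartile scaling for both), but with an estimated correlation the adjusted p of both was 0.765 in the unscaled fit.

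**Figure D4:**
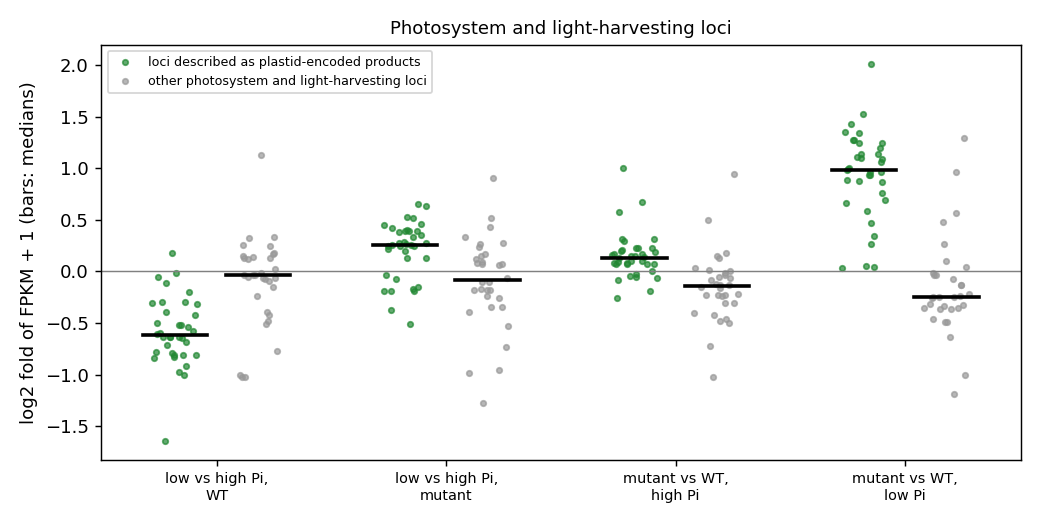
Log2 folds on the log2(FPKM + 1) scale (y axis) of 36 copies of plastid-encoded photosystem genes (green) and 32 nuclear-encoded ones (grey) in 4 contrasts (x axis); each point is a gene and bars are medians. In the mutant against WT at low Pi the medians were 0.99 and −0.25, and in WT at low against high Pi −0.62 and −0.03; these medians kept their signs under both scalings of FPKM.

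At low Pi, limma called 2796 genes (15.9%), 833 up and 1963 down, with 213 and 459 past a log2 fold of 1. Of these, 2766 had no overlap between groups (37.8% of tested genes, against 10% by chance). The split of directions depended on scaling, with 1340 up and 1404 down after median-of-ratios and 1165 up and 1619 down after upper-quartile scaling (29.8, 48.8 and 41.9% up). The count was 1761 and 1274 without WT low-Pi library 2 or 3, and 1325 and 1454 without mutant low-Pi library 1 or 2. With a pseudocount of 0.1, 318 rises and 711 falls passed a log2 fold of 1, and without WT low-Pi library 3 these were 152 and 305.

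The mutant effects at high and low Pi, which share no library, were then compared. Genes lower in the mutant at both Pi levels numbered 169, against 44.6 expected from independent lists, and genes higher at both 70, against 10.9. Another 63 moved in opposite directions, for which no expected number was computed. The lists are not independent here either, because of the shared variance, so these expected numbers may be too low as well. With each library left out in turn, the genes called in both in the same direction ran from 79 to 307, against 239 with all libraries. Across genes, which are not independent replicates, the folds correlated with r = 0.339 and rho = 0.296. With each library left out in turn, r ran from 0.226 to 0.425. LOC_Os06g51220 and LOC_Os08g28670 were lower in the mutant at both levels.

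Whether the response to low Pi differed between genotypes was tested by the interaction. Trehalose-phosphate synthase LOC_Os02g54820 went from 31.6 ± 6.66 to 10.3 ± 5.59 FPKM in WT and from 10.8 ± 2.94 to 38.6 ± 1.87 in the mutant (interaction 3.41, SE 0.43, adjusted p = 0.00296). The expansin LOC_Os03g04020 went from 83.8 to 19.7 in WT and from 30.4 to 78.5 in the mutant (3.53, SE 0.48, adjusted p = 0.00425). The calmodulin-like OsCML10 (LOC_Os01g72100) went from 43.2 to 138 FPKM in WT and from 49.97 to 22.3 in the mutant (−2.81, SE 0.29, adjusted p = 0.000917). A DUF581 protein (LOC_Os04g49660) went from 10.9 to 43.0 and from 22.3 to 7.75 (−3.38, SE 0.36, adjusted p = 0.00103). The HD-Zip gene LOC_Os09g29460 went from 70.2 to 218 and from 109.5 to 48.7 (−2.84, SE 0.40, adjusted p = 0.00524). The cytochrome P450 LOC_Os02g47470 had an interaction of −4.78 (SE 0.83, adjusted p = 0.0116).

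Of 59 core histone, replication and mitosis genes, the interaction was called in 8, all negative (19 negative and 1 positive adjusted over the list alone; median −0.42, camera adjusted p = 0.000939, and adjusted p = 0.983 with an estimated correlation). The histone H3 gene LOC_Os06g04030 went from 288 to 579.6 FPKM in WT and from 635 to 241 in the mutant (−2.26, adjusted p = 0.0123), and LOC_Os07g36130 had −2.64 (adjusted p = 0.00984). Of 68 photosystem genes, the interaction was called in 4, all positive (20 positive and 1 negative adjusted over the list alone; median 0.20, camera adjusted p = 4.73e-06, and adjusted p = 0.677 with an estimated correlation). LOC_Os04g16876 had 2.27 (adjusted p = 0.0119). The calls of the other 3 depended on single libraries. LOC_Os04g16872 (adjusted p = 0.0482) was lost in 10 of 12 fits without 1 library, all but those without WT low-Pi library 1 or mutant low-Pi library 3, and reached 0.125 without WT low-Pi library 3. LOC_Os06g39708 (1.43, adjusted p = 0.0329) was lost without WT high-Pi library 2 (0.0826) or 3 (0.0648), WT low-Pi library 2 (0.0745) or 3 (0.0873), mutant high-Pi library 1 (0.0523) or 2 (0.0794), or mutant low-Pi library 1 (0.0823) or 2 (0.0872). LOC_Os09g04680 (1.09, adjusted p = 0.0241) was lost without WT high-Pi library 2 (0.0687) or 3 (0.0507), WT low-Pi library 3 (0.0668), mutant high-Pi library 2 (0.0624), or mutant low-Pi library 1 (0.0642) or 2 (0.0577). With no filter the adjusted p of these 3 genes was 0.0889, 0.0655 and 0.055. All 4 were copies of plastid-encoded genes (median 0.89 over 36), while the nuclear-encoded genes had a median of −0.03 that turned positive under both scalings. Of 333 ribosomal protein genes, 1 was positive and 1 negative (1 and 1 adjusted over the list alone; median 0.11, camera adjusted p = 0.00867, and adjusted p = 0.983 with an estimated correlation). The latter was LOC_Os03g52400 (−1.45, adjusted p = 0.0143), and the former LOC_Os01g70010 (1.14, adjusted p = 0.0179). The call of LOC_Os01g70010 was lost without WT high-Pi library 2 (0.0559) or mutant high-Pi library 2 (0.0522) within a range of 0.0132 to 0.0559. The 6 ZIM domain genes had a median interaction of −0.49 (camera adjusted p = 0.794).

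For the interaction, limma called 641 genes (3.64%), 263 positive and 378 negative, with 192 and 162 past a size of 1 on the log2 scale. After median-of-ratios scaling 358 were positive and 311 negative, and after upper-quartile scaling 318 and 363 (41.0, 53.5 and 46.7% positive). The count was 259 and 370 without WT high-Pi library 2 or 3, 420 and 304 without WT low-Pi library 2 or 3, 298 without mutant high-Pi library 2, and 340 and 281 without mutant low-Pi library 1 or 2. With a block for the replicate number it was 391 (163 positive and 228 negative). With no filter it was 366, and 119 positive and 102 negative ones passed a size of 1. Without WT low-Pi library 1, 434 genes were positive, and past a size of 1 there were 302 positive and 228 negative genes, against 212 and 301 without WT high-Pi library 1. These were 104 and 86 without WT high-Pi library 2, 118 and 93 without WT low-Pi library 3, 113 and 96 without mutant high-Pi library 2, and 111 and 97 without mutant low-Pi library 2. Without mutant low-Pi library 1, 140 positive genes passed a size of 1, and the negative genes past that size were fewer by over 1.5 times.

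The authors' deposited tables marked genes as changed in the same 4 pairwise comparisons. For low against high Pi in WT, the authors' deposited table marked 1264 genes (713 higher, 551 lower), of which 1054 were tested here and 827 called. The authors' deposited table for the mutant marked 1572 (890 higher, 682 lower), with 1351 tested and 1018 called here. At high Pi, the authors' deposited table marked 950 genes (246 higher and 704 lower in the mutant), of which 773 were tested and 264 called. At low Pi, the authors' deposited table marked 1622 (501 and 1121), of which 1398 were tested and 1013 called. Among genes called here and marked in the authors' deposited tables, 0 had opposite directions. The marks and the calls come from the same libraries, so this count is no independent check. Marked genes in the authors' deposited tables had p up to 0.05 and a log2 fold of at least 1 in size. Their q in the authors' deposited tables reached 0.23 and 0.19 for the responses in WT and the mutant, and 0.34 and 0.17 for the mutant at high and low Pi.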

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

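Of the tests in this part, those on the copies of plastid-encoded genes, on the nuclear-encoded genes and on both scalings of FPKM were chosen only after the result was seen. The response to low Pi differed between WT and mutant in 641 genes by the interaction term, and 10 named genes were taken up for the same reason. So were 3 lists by camera at the preset correlation (photosystem, core histone with replication and mitosis, and ribosomal protein genes), but with an estimated correlation their adjusted p was 0.677, 0.983 and 0.983. Groups of 3 are too small for a test of single outlying libraries. Of 100 splits with genotype labels exchanged within Pi levels, 3 gave as many genes, the real one included. This share leaves open whether chance can be excluded, because splits that mix genotypes carry the genotype effect in their spread within groups and call few genes for that reason. The highest of the other splits gave 2957 genes. That split exchanged all genotype labels at low Pi and left those at high Pi in place, so its interaction is the sum of the mutant effects at both Pi levels. Its size points to a structure of the samples, the genotype effect, which called 2796 genes at low Pi alone. The second highest, with 1062 genes, exchanged 1 further library at high Pi.

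Positive interactions were found for OsFBX404 (LOC_Os11g09590, 4.95 on the log2(FPKM + 1) scale, adjusted p = 0.00369), a value that depends on the pseudocount since the gene was listed at 0 in all 6 high-Pi libraries and in 2 WT libraries at low Pi. The phosphatase LOC_Os03g49440 had 3.89 (adjusted p = 0.0215), lost without WT high-Pi library 2 (0.0633), WT high-Pi library 3 (0.0537), mutant high-Pi library 2 (0.0551) or mutant low-Pi library 2 (0.0595), within a range of 0.00557 to 0.0633. The expansin LOC_Os03g04020 had 3.53, trehalose-phosphate synthase LOC_Os02g54820 3.41 and the thioredoxin LOC_Os07g48510 3.31, the last lost without WT high-Pi library 2 (0.0522; range 0.00374 to 0.0522). Negative interactions were found for the cytochrome P450 LOC_Os02g47470 (−4.78), the DUF581 protein LOC_Os04g49660 (−3.38), the HD-Zip gene LOC_Os09g29460 (−2.84) and OsCML10 (LOC_Os01g72100, −2.81). The DUF584 protein LOC_Os07g33270 had −3.69 (adjusted p = 0.0219), lost without WT high-Pi library 2 (0.0643), mutant high-Pi library 2 (0.0551), mutant low-Pi library 1 (0.0547) or mutant low-Pi library 2 (0.062), within a range of 0.00452 to 0.0643. Among lists, the median interaction was −0.42 for core histone, replication and mitosis genes and 0.11 for ribosomal protein genes.

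The photosystem list had a median interaction of 0.20, which came from copies of plastid-encoded genes. Of these copies, 9 of 36 fell at low Pi in WT (median −0.62, adjusted p = 0.201 with an estimated correlation) and 27 were higher in the mutant than in WT at low Pi (adjusted p = 0.117 with an estimated correlation). Their mean difference of 0.94 at low Pi is the sum of 0.15 at high Pi and 0.21 from the response of the mutant, less the WT response of −0.58. Scaling of the libraries was argued against as the whole cause, since the median of the copies stayed at 1.03 or more under both scalings. The nuclear-encoded photosystem genes had a median of −0.25 between genotypes at low Pi, so as a set they did not share the difference. A candidate explanation is that reads from plastid transcripts were counted at nuclear copies, with plastid RNA captured in unequal amounts between groups; this was not separated from a difference in plastid transcript level, and a change of plastid transcription with genotype and Pi stays open and untested.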

How the results depend on the processing

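Both scalings of FPKM, the filter at FPKM 5 and, for the comparison of folds between contrasts, the pseudocount of 0.1, the omitted filter and the left-out libraries were tests chosen only after the data had been seen. The count-based normalizations, the count test, the CPM filter and the omission of organelle genes were not run, since the values used were FPKM and no chromosomes were used. No called named gene reversed its direction under any alternative, and 35 of 46, 37 of 41, 11 of 30, 30 of 37 and 12 of 20 called named genes stayed past the threshold in all of them in the order WT, mutant, mutant effect at high Pi, mutant effect at low Pi and interaction. With 1 library left out at a time, calls ranged from 1147 to 2622 (WT, with all libraries 2345), 1984 to 3321 (mutant, 3307), 177 to 851 (high Pi, 631), 1274 to 3073 (low Pi, 2796) and 259 to 878 (interaction, 641), with fewer samples as one cause. For the low-Pi responses, r ran from 0.380 to 0.517, rho from 0.258 to 0.405 and shared calls from 734 to 1144 (1152 with all libraries). For the mutant effects r ran from 0.226 to 0.425, rho from 0.220 to 0.341 and shared calls from 79 to 307 (239 with all). Replicate numbers did not pair libraries. Over 12 pairs the correlation of deviations ran from −0.383 to −0.0043, 0 exceeded 0.1 and 0 correlated best with their own number. With a block for that number, calls went to 1763, 2633, 312 (high Pi), 2165 and 391 (interaction) and shared mutant effects to 130. The filter at FPKM 5 tests fewer genes and gave 417 calls at high Pi, 159 shared mutant effects and rho = 0.235. A fit to only the 6 libraries gave 103 at high Pi, no filter gave 366 for the interaction, and a pseudocount of 0.1 gave r = 0.425 for the mutant effects (0.339 with 1). Of 27 lists, camera called 4, 2, 4, 1 and 3 in the order above. With an estimated correlation it called 0 in each, and fry, which does not compare a list with other genes, called 8, 4, 0, 6 and 0. For the mutant response 0 lists were called under the block or either scaling. For the mutant at low Pi 2 were called under the block and 3 under median-of-ratios and under upper-quartile scaling. Except where fewer genes or samples entered, the cause was not tested. Depth is unknown, so no limit from read number could be set for weakly expressed genes.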

Other observations

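Of the tests in this part, those on the added clock and ZIM lists, on GO and KEGG terms, on the spread within groups and on the harvest hour, and both scalings of FPKM, were chosen only after the result was seen. Of 81 auxin genes, 3 rose and 9 fell in the mutant at low Pi (4 and 11 adjusted over the list alone; camera adjusted p = 0.364). Of 61 gibberellin and brassinosteroid genes, 5 rose and 11 fell (7 and 17 adjusted over the list alone; camera adjusted p = 0.407). Of 39 ethylene genes 8 fell (8 adjusted over the list alone; camera adjusted p = 0.283), and of 16 cuticle and epidermis markers 5 fell (6 adjusted over the list alone; camera adjusted p = 0.319). Of 29 cell wall and expansin genes, 3 rose and 4 fell (4 and 4 adjusted over the list alone). Of 19 Calvin cycle genes 5 rose (5 adjusted over the list alone; median 0.02, camera adjusted p = 0.186), and of 8 chlorophyll metabolism genes 2 rose (2 up and 1 down adjusted over the list alone). Of 4 S-like ribonucleases 1 fell. Within WT at low Pi, 2 of 23 sugar and starch genes rose and 4 fell (2 and 5 adjusted over the list alone), and 7 of 102 heat shock and chaperone genes rose and 9 fell (7 and 9 adjusted over the list alone). Of 7 vascular and lignin markers, 1 rose at low against high Pi within the mutant (0 adjusted over the list alone). Within the mutant, 44 of 333 ribosomal protein genes rose and 5 fell at low Pi (34 and 3 adjusted over the list alone; median 0.11, camera adjusted p = 0.0692), among them L21 of the chloroplast (LOC_Os05g48410, 1.03, adjusted p = 0.00136). Root markers had 0 tested genes. Of 21 iron deficiency genes by GO, added later, 5 rose and 4 fell in WT and 4 rose and 5 fell in the mutant at low Pi.

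Of 1309 GO and KEGG terms with 8 to 600 tested genes, camera called 16, 3, 4, 5 and 21 in WT, the mutant, the mutant at high Pi, the mutant at low Pi and the interaction, and 0 held with an estimated correlation. In WT at low Pi, 12 of 49 rRNA processing genes rose and 1 fell (median 0.27, camera adjusted p = 0.0153), and 9 of 18 genes of mitochondrial mRNA modification rose (0.42, adjusted p = 0.0128). Pseudouridine synthesis genes rose in 5 of 11 cases in WT and 7 of 11 in the mutant (median 0.47 in the mutant, camera adjusted p = 0.0199). At low Pi, 25 of 56 genes annotated with the response to chitin fell in the mutant and 1 rose (median −0.63, camera adjusted p = 0.000151, and adjusted p = 0.998 with an estimated correlation). For the interaction, 5 of 23 tricarboxylic acid cycle genes were negative (median −0.37, camera adjusted p = 0.0039) and 3 of 9 trehalose-phosphate synthase genes positive (0.75, camera adjusted p = 0.0176), with adjusted p = 1 for both with an estimated correlation.

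For each of the comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split was the 1 with the most genes in each case: 2345 in WT (highest other 3), 3307 in the mutant (15), 631 at high Pi (1) and 2796 at low Pi (3). The other splits mix the real groups, so the real difference enters their spread within groups and they call few genes for that reason. These counts therefore do not decide whether chance can be excluded.

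Some genes of the circadian clock moved with Pi. The fixed clock list held 3 tested genes (WT median −0.10, mean 0.05, camera adjusted p = 0.826, and 0.413 in the mutant). Of these, GIGANTEA (LOC_Os01g08700) rose in the mutant (163 to 294 FPKM, 0.85, adjusted p = 0.00614) and in WT (179 to 304, 0.75, adjusted p = 0.0159; lost without WT high-Pi library 2 at 0.0532, WT high-Pi library 3 at 0.0514 or WT low-Pi library 1 at 0.0534, range 0.0106 to 0.0534). In the added lists, 2 of 5 morning genes fell in each genotype, with a median of −0.65 in WT and −0.49 in the mutant (camera adjusted p = 1.17e-05 and 0.00634, and adjusted p = 0.00913 and 0.0834 with an estimated correlation). Of 9 day and evening genes, 6 rose in WT and 7 in the mutant, and the medians were 0.75 and 1.06 (camera adjusted p = 0.000161 and 7.79e-05, and adjusted p = 0.134 and 0.0903 with an estimated correlation). The p-values of both lists were adjusted over the 6 added lists alone. Scaling was argued against for the added lists, since the smallest of their medians within WT and within the mutant was 0.49 in size under either scaling. The gap of 1.40 between the medians in WT may reflect leaves collected at another hour for the Pi levels or a clock phase that Pi supply shifts. The hour of harvest is not given in the sources used here, so these explanations were not separated, and an effect of Pi on the clock stays open and untested.

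All 6 ZIM domain genes and 25 of 56 chitin-response genes, many of which respond fast to touch and wounding, fell in the mutant at low Pi. With an estimated correlation the groups had adjusted p of 0.247 and 0.998. At high Pi the chitin-response means of the mutant (2.51, 2.60 and 2.19) overlapped those of WT (3.30, 2.39 and 2.75). The ZIM means of the mutant (1.01, 2.16 and 0.96) lay below those of WT (4.70, 2.39 and 3.20) at high Pi. The 2 ZIM calls at high Pi were lost on leaving out single libraries, although their folds stayed at −2.77 and −2.37 or lower over the alternatives. A difference of hour between genotypes large enough to give a gap of 1.40, as between Pi levels, was argued against. The larger gap of clock medians between genotypes was 0.39 in size. Whether the gap of 1.40 came from the hour is not known, so it cannot be used to size a smaller difference. A smaller difference of hour stays open, since 1 of 5 morning genes was higher in the mutant at low Pi (list median 0.34, camera adjusted p = 0.0094, and adjusted p = 0.117 with an estimated correlation). At high Pi the median of the morning genes was 0.17. LOC_Os08g06110, of the LHY orthology group, stood at 476 ± 24.7 FPKM in the mutant and 275 ± 20.9 in WT at high Pi. At low Pi it stood at 68.6 ± 6.90 and 37.7 ± 8.90. Uneven handling of leaves at collection may contribute. The median SD of chitin-response genes within groups was 0.351 on the log2 scale, against a median of 0.189 in 10000 random gene sets, all of which lay below it. The random sets were matched on mean expression only. The larger spread therefore cannot tell handling from other variation between the libraries of a group. The mean of ZIM genes ranged from 2.39 to 4.70 among WT libraries at high Pi. In the mutant at low Pi the ZIM means were 0.89, 1.00 and 1.03, and the chitin-response means 2.03, 2.23 and 2.13, below every WT library. Handling that differed by group is confounded with genotype, and an effect of OsHMGB1 on these genes stays open and untested.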
